A study of Homo sapiens with 4 samples.

How the data were processed

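Chromatin accessibility was measured by ATAC-seq, in which the transposase Tn5 inserts sequencing adapters into open chromatin. The material was cortical organoids at day 14, grown from the human embryonic stem cell line H9. There were 4 libraries. A pair came from unedited H9 organoids (CHD7 +/+, called WT here), and a pair came from H9 organoids in which CHD7 had been knocked out with CRISPR-Cas9 (CHD7 -/-, called KO). Per the labels' protocols, each reaction pooled 4 organoids and used 50000 viable cells in an Omni-ATAC preparation. Groups and replicate numbers were taken from the sample titles. The labels do not say whether replicates came from separate cultures or clones, so the spread between replicates may be partly technical. The peak names inside both deposited KO lists carry a further code that those of the WT lists lack, the same in both apart from the replicate number; whether it marks a clone or a batch is not given in the sources used here.

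The deposited data are a peak list for each library, so peaks were called per library and not on pooled samples. Trim Galore 0.4.4, Bowtie2 2.3.4.1, SAMtools 1.8, MACS2 2.1.2 and DiffBind 2.10.0 are named in the submitters' processing notes, without their settings. The peak names inside the deposited files record paired-end reads, duplicate removal, removal of mitochondrial reads and a q threshold of 0.05, and the lowest −log10 q in the lists was 1.30. Coordinates were on hg19, per the submitters' processing notes and the contig names in the files; the notes also name mm10, a mouse build, with no role given. For each peak the deposited files hold the interval, the summit, the fold enrichment at the summit over the local background of the same library, the −log10 p and −log10 q at the summit, and a display score. The deposited score was the −log10 q times 10 with decimals dropped, in every peak used, and was not analysed further. Fold enrichment and −log10 q are the authors' values for each peak within its own list. They were used to describe, rank and filter peaks, and no change at a single region was tested with them. Fold enrichment also served, with −log10 p, to solve for pileup and background. Median folds over common regions were compared between libraries without a p-value.

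Read totals are not part of the peak lists. MACS2 computes the fold as the summit pileup plus 1 over the background plus 1, and the p-value from a Poisson distribution of the same quantities, so both were solved for each peak. Whole-number pileups that gave the deposited −log10 p to within 0.01 were found for 100% of peaks in each list. The background below which MACS2 does not go was then read off as the 1st percentile of the solved backgrounds. It was 0.87 and 0.953 overlapping fragments in WT replicates 1 and 2, and 0.768 and 0.787 in KO replicates 1 and 2. This background is proportional to the number of fragments times their length. The narrowest peak was 183, 193, 170 and 178 bp in the same order. Intervals given for counts of regions cover the sampling of regions along the genome and not the spread between cultures.

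Peaks on chromosomes 1 to 22 and X were used, which left out between 466 and 641 peaks per list on Y, unplaced contigs and alternative haplotypes. The 4 lists were joined into merged regions wherever peaks overlapped by at least 1 bp, and a library had a region when it had a peak in it. Regions with a peak in both WT libraries and in neither KO library are called WT-only, and the opposite case KO-only. Regions found in exactly 1 WT and 1 KO library (4 mixed pairs) show how often a pair of libraries shares a region alone without a genotype in common. The pair excess is the product of the WT-only and KO-only counts over the product of complementary mixed pairs, as the geometric mean of both complementary sets. A factor that acts alike on the odds of calling each region in a library cancels in it. Its 95% interval came from 1000 bootstrap draws of 5 Mb blocks. Similarity of lists was measured by the Jaccard index of covered bases. Group means were compared with exact permutation tests, which with 2 against 2 libraries cannot give a p below 0.333. Chromosomes were compared by Fisher's exact test. Cytogenetic bands (851 hg19 bands on the chromosomes used, from circlize 0.4.16) were compared by an exact binomial test where they held at least 8 WT-only or KO-only regions. Both were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Tests of chromosomes, bands and band groups count regions, which are not independent replicates. Their p-values do not measure the spread between cultures.

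The tests, gene lists and alternatives were chosen before the data were examined. An hg19 genome and annotation were not used here. The planned assignment of regions to genes, the promoter shares, the 21 gene lists, the test of single genes and the 25 sequence motifs were therefore not analysed here. Bands took the place of genes after this was known. The rule for named items was kept for what could be placed: the 10 WT-only and 10 KO-only regions with the highest lower −log10 q of the pair, and the 10 bands with the smallest p in each direction. Bands that hold well-known developmental genes were added after the genome-wide counts had been seen, with gene positions from general knowledge and the chromosome of each gene checked against a RefSeq gene table (GRCh38.p14) whose coordinates were not used. The bands of this set are given individually, except for 2 that are not reported here and enter the group totals.

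Alternatives were a stricter peak threshold (−log10 q of at least 5), lists cut to the 47819 strongest peaks each, a requirement that a library's peaks cover at least 50% of a region, merging across gaps of 500 bp, all contigs, and leaving out each library. A common minimum peak width of 193 bp, and thinning of all lists to the lowest background of 0.768 with a −log10 p threshold of 3.37 (mean of 20 draws), were added after seeing the data, as were the comparisons of list lengths and regions within same-numbered pairs and the shares of peaks found in lists of equal length. Thinning redrew each peak's summit pileup and left peak widths as they were. The code was tested on simulated data. With 101594 simulated regions and no genotype effect the pair excess was 1.09 (95% interval 0.983 to 1.20). With 200 regions made WT-only and 200 made KO-only, it was 1.42 (1.31 to 1.54), and 97% of the simulated WT-only regions were recovered. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.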

Results

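Chromatin accessibility was compared between cortical organoids grown from H9 human embryonic stem cells and from H9 cells lacking CHD7, a chromatin remodeler of the chromodomain helicase family. Day 14 lies early in cortical differentiation, and 2 libraries were available per genotype. After exclusion of Y and unplaced contigs, the lists held 61112 and 72946 peaks in WT replicates 1 and 2, and 47819 and 51105 peaks in KO replicates 1 and 2. The peaks covered 34.7 and 43 Mb in the WT libraries and 26.7 and 29.1 Mb in the KO libraries. The lists themselves carry no read totals. The background pileup solved from them, which reflects fragment number and fragment length together, was 0.912 ± 0.0581 (SD, n = 2) in WT and 0.778 ± 0.0132 (SD, n = 2) in KO. Relative to WT replicate 2 it was 0.914 in WT replicate 1, and 0.807 and 0.826 in KO replicates 1 and 2. Divided by the narrowest peak width of each list, these values were 0.964, 0.916 and 0.896. The gap in fragment number may therefore be smaller than the gap in background, if the narrowest width follows fragment length.

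CHD7 itself could not be examined for the knockout, since peak lists show neither its transcript nor the edited sequence. Its band, 8q12.2, spanned 0.6 Mb and held 15 regions with a peak in all 4 libraries, 4 WT-only regions and 1 KO-only region.

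Fewer accessible regions were called in the knockout organoids. The WT lists held 67029 ± 8368 peaks and the KO lists 49462 ± 2324 peaks (SD, n = 2 each), a ratio of 1.36 (two-sided exact permutation test, p = 0.333, the smallest that 2 against 2 libraries can give). Both WT lists were longer than both KO lists. Covered bases followed, at 38.9 ± 5.88 Mb in WT and 27.9 ± 1.72 Mb in KO (SD, n = 2 each; p = 0.333 in the same exact test). Median peak width was 463.5 ± 16.3 bp in WT and 447 ± 11.3 bp in KO (SD, n = 2 each), which did not separate the genotypes (exact permutation p = 0.667). Background pileup also differed between the genotypes in the same direction, by a factor of 1.17. With the summits of all lists thinned to the same background, and peak widths left as they were, the ratio of list lengths was 1.28.

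Libraries of the same genotype shared more open chromatin than libraries of different genotypes. The Jaccard index was 0.496 between the WT libraries and 0.503 between the KO libraries. The 4 pairs of different genotype lay between 0.413 and 0.452. The mean of the same-genotype pairs exceeded the mean of the others by 0.0656. Pairing the libraries by replicate number gave a difference of -0.0304, and the crossed pairing gave -0.0352. The genotype pairing was the highest of these 3 possible pairings, a share of 0.333, which is the smallest this design allows.

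The 4 lists merged into 101594 regions, of which 28147 (27.7%) had a peak in every library. A further 9923 regions were WT-only, and 2347 were KO-only. Thus 21.5% of the 46135 regions found in both WT libraries had no peak in either KO library, whereas 6.91% of the 33987 regions found in both KO libraries had none in either WT library. WT-only regions were 4.23 times as numerous as KO-only regions, and 3.56 times (± 0.0166, SD of 20 draws) after thinning to equal background. The size of this ratio depended on the lists: it was 1.43 with lists of equal length, 1.38 without KO replicate 1, 1.7 without KO replicate 2, 8.34 without WT replicate 1 and 4.43 without WT replicate 2. Leaving out a library loosens both classes, so these ratios compare differently defined classes. The mixed pairs shared between 982 and 2597 regions alone. The WT-only count was 3.82 times the highest of these. The KO-only count lay below that highest mixed pair, WT 2 and KO 2, and above the other 3.

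**Figure D1:**
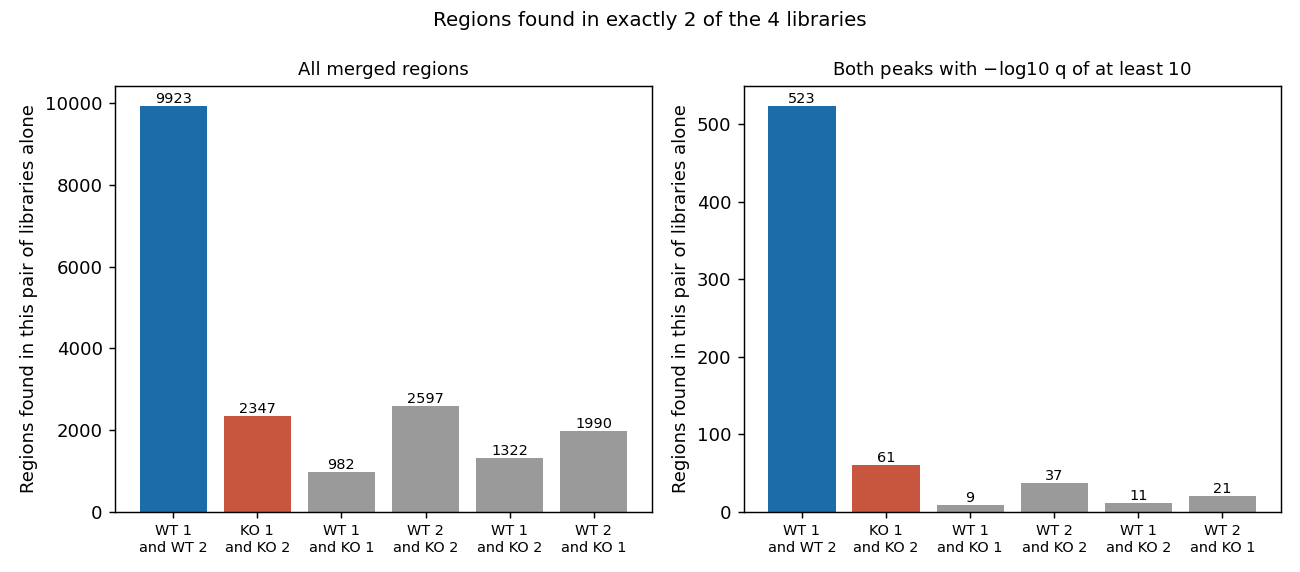
Bars give the number of merged regions (linear axis from 0) with a peak in the named pair of libraries and in no other library; the left panel takes all regions and the right panel those whose peaks both reach a −log10 q of 10. Blue is the WT pair (9923 and 523 regions), red the KO pair (2347 and 61), and grey the 4 pairs of 1 WT and 1 KO library.

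Because list lengths differed, the pair excess was used to compare same-genotype with mixed pairs. A library factor cancels in it only where it acts alike on the odds of calling each region. The pair excess was 8.99 (95% interval 8.34 to 9.67). In simulated lists with no genotype effect it was 1.09. Those lists were drawn independently with a single factor per library, so a value near 1 was built in. They check the code and are not a null for these libraries. The complementary sets gave 9.13 with same-numbered and 8.85 with cross-numbered mixed pairs. Among regions whose 2 peaks both reached a −log10 q of 10, 523 were WT-only, 61 were KO-only and 78 belonged to a mixed pair. The ratio of WT-only to KO-only was 8.57 among these strong regions, and their pair excess was 115 (68.7 to 249). The WT lists also held more peaks at this level (mean 23147.5 against 16325.5 in KO, a ratio of 1.42), so 8.57 includes list-wide differences.

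By median fold in each WT list, WT-only regions were weaker than regions found in all 4 libraries and stronger than regions of mixed pairs. Regions called in all 4 libraries are strong in part by selection. Their median fold enrichment was 5.05 in the list of WT replicate 1 and 5.19 in that of WT replicate 2, whereas regions found in all 4 libraries had medians of 7.61 and 7.75 in the same lists. KO-only regions had medians of 4.9 and 5.04 in the KO lists, against 6.96 and 7.12 for regions found in all 4. Median region width was 524 bp for WT-only, 457 bp for KO-only, 459 bp for mixed pairs and 982 bp for regions in all 4 libraries. A region spans all peaks merged into it, so regions built from more lists, or from wider peaks, tend to be wider by construction. The fold of a region is the highest of each list's peaks in it. At a −log10 q of at least 10 stood 10.1% and 15% of the WT-only regions in WT replicates 1 and 2, and 6.01% and 8.99% of the KO-only regions in KO replicates 1 and 2. Regions of mixed pairs, also found in exactly 2 libraries, had median folds of 4.42 and 4.62 in the WT lists and 4.52 and 4.48 in the KO lists. Of the mixed-pair regions, 4.17% and 8.61% reached that −log10 q in the WT lists, and 2.25% and 3.62% in the KO lists.

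The strongest sites stayed open in both genotypes. Of the strongest 10th of peaks in WT replicate 1, 99.9% were found in each KO library, and 6 of 6112 were in neither. Below the strongest deciles the shares parted. In the 2nd decile from the weak end of WT replicate 1, 48.9% of peaks were found in WT replicate 2, 24.6% in KO replicate 1 and 27.5% in KO replicate 2, and in the 5th decile the shares were 81.8%, 49.6% and 53.1%. In the 7th decile of WT replicate 1, 93.5% of peaks were found in WT replicate 2, but 70.1% in KO replicate 1 and 73.2% in KO replicate 2. In the same decile of WT replicate 2 the shares were 84.2%, 60.8% and 64.7%. These shares depend on the lengths of the lists, since the longer WT lists hold more peaks to be found in. In the 7th decile of KO replicate 1, 91.7% were found in KO replicate 2, 87.5% in WT replicate 1 and 91% in WT replicate 2. In the 7th decile of KO replicate 2 the shares were 86.8% in KO replicate 1, 85.2% in WT replicate 1 and 89.9% in WT replicate 2. With each list cut to its 47819 strongest peaks, the library of the same genotype held the most in this decile for each of the 4 libraries. For WT replicate 1 the shares were then 94.4% in WT replicate 2 against 79.8% and 81.2% in the KO libraries, and for WT replicate 2 they were 92.7% against 80.2% and 82.5%. For KO replicate 1 they were 91.4% in KO replicate 2 against 84.6% and 85.6% in the WT libraries, and for KO replicate 2 they were 89.4% against 84.4% and 86.3%. Over the 10 deciles this order did not hold in the weakest decile of KO replicate 2, with 29% in KO replicate 1 and 30.2% and 29.8% in the WT libraries.

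**Figure D2:**
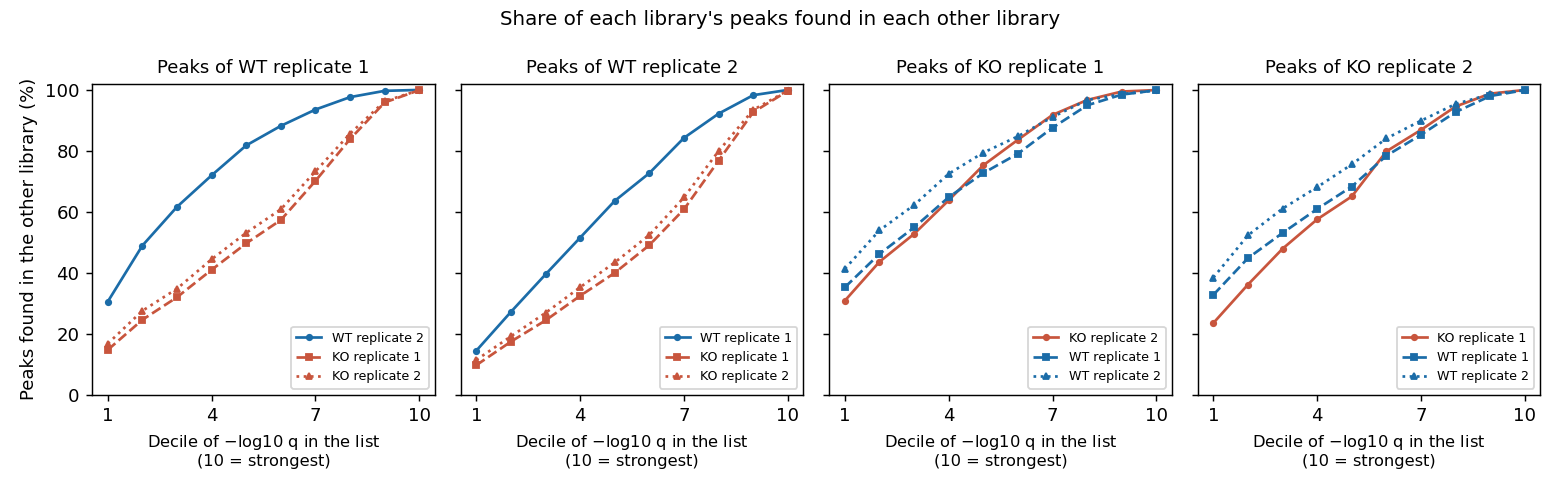
Each panel takes the peaks of one library, split into 10 equal groups by −log10 q (x axis, 10 the strongest), and plots the percentage found in each other library (y axis), with blue lines for WT and red lines for KO libraries. In the WT panels the other WT library lies above both KO libraries in every decile, narrowly in the strongest. In the 7th decile of WT replicate 1 the shares are 93.5% against 70.1% and 73.2%. In the KO panels, with lists of unequal length, the order changes with strength. In the weakest decile of KO replicate 2 the WT libraries hold more (32.8% and 38.4%) than KO replicate 1 (23.5%). In its 7th decile the shares are 85.2% and 89.9% in the WT libraries and 86.8% in KO replicate 1.

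The single WT-only region with the highest significance lay on chromosome 2 at 37762968 to 37763612 in band 2p22.2, with fold enrichments of 15.6 and 16 in the WT replicates. It was followed by chromosome 2, 179387564 to 179388638 (2q31.2), with folds of 15 and 11.8, and by chromosome 6, 3849159 to 3850045 (6p25.2), with folds of 13.3 and 12.1. Chromosome 2 also held the regions at 87841861 to 87842653 (2p11.2, folds 11.2 and 10.4), 166428750 to 166429019 (2q24.3, folds 8.65 and 7.37) and 170870407 to 170870905 (2q31.1, folds 12 and 11). The rest of the leading 10 were chromosome 3, 182415137 to 182415877 (3q26.33, folds 12.1 and 11.3), chromosome 7, 76961233 to 76961843 (7q11.23, folds 11.5 and 10.7), chromosome 1, 105642205 to 105643041 (1p21.1, −log10 q 22.6 and 29.9), and chromosome 5, 30373234 to 30373770 (5p13.3, folds 11.5 and 10.5). No peak was called at any of these 10 positions in either KO library. Whether they are promoters, introns or intergenic sites was not analysed here.

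Among KO-only regions, the leading entry was a 182 bp region on chromosome 8 at 70602342 to 70602523 (8q13.3), with a fold of 25.3 and 25.4 in the KO replicates. It was narrower than the narrowest peak of either WT list (183 and 193 bp), so whether the site was open in WT could not be read from the lists. The next were chromosome 4, 330883 to 332267 (4p16.3, folds 9.62 and 8.66), chromosome 11, 125024191 to 125024923 (11q24.2, folds 9.64 and 10.5), chromosome 8, 34968691 to 34969538 (8p12, folds 13.2 and 10.2), and chromosome 4, 14603678 to 14604397 (4p15.33, folds 10.2 and 12). The remaining 5 were chromosome 13, 60227802 to 60228524 (13q21.2, folds 9.11 and 11), chromosome 6, 122813202 to 122813528 (6q22.31, folds 10.3 and 12.5), chromosome 18, 14450173 to 14450933 (18p11.21, folds 11 and 9.24), chromosome 14, 77525661 to 77526188 (14q24.3, folds 11.5 and 8.93), and chromosome 22, 39040331 to 39040565 (22q13.1, folds 10.7 and 13.8). The lower −log10 q of the pair was 184 for the leading KO-only region, far above all the others named, for a reason that was not tested. It ranged from 16.4 to 21 over the KO-only regions ranked 2 to 10, and from 21.4 to 43.6 over the 10 WT-only regions.

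The surplus of WT-only regions was spread over the genome. On each of the 23 chromosomes WT-only regions made up between 77% (chromosome 8) and 87.5% (chromosome 21) of the WT-only and KO-only regions together, against 80.9% overall. Chromosome 4 stood at 85%, with 673 WT-only and 119 KO-only regions (Fisher's exact test over regions, which are not independent replicates, two-sided, Benjamini-Hochberg adjusted p = 0.0469 over 23 chromosomes). The call ended in the same exact test at the stricter peak threshold (adjusted p = 0.878), with the 50% cover rule (0.301), with a common minimum width (0.137) and without WT replicate 1, WT replicate 2 or KO replicate 2 (0.277, 0.0864 and 0.256). With lists thinned to equal background, chromosome 4 passed in 15 of 20 draws (adjusted p from the same exact test 0.02 to 0.14). No other chromosome passed, and 6, chromosome 4 included, had an unadjusted p below 0.05. Without KO replicate 1, 2 chromosomes passed.

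**Figure D3:**
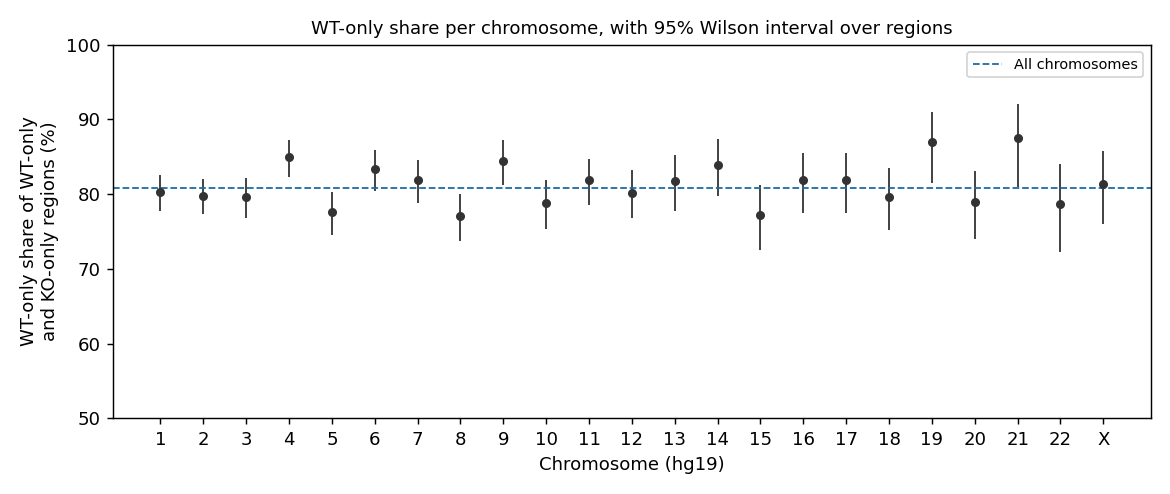
Points give the share of WT-only regions among WT-only and KO-only regions (percent, axis from 50 to 100) on each hg19 chromosome, bars the 95% Wilson interval over regions, and the dashed line the share over all chromosomes, 80.9%. All chromosomes lie between 77% and 87.5%.

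Of 616 bands with enough regions, 612 held more WT-only than KO-only regions. No band differed from the genome-wide share after adjustment (exact binomial test, smallest adjusted p = 0.225), and 25 had an unadjusted p below 0.05, of which 6 leaned to WT and 19 to KO. A count of 25 among 616 is no more than a threshold of 0.05 would allow without any skew. Against a high WT-only share, the test reaches a low p more readily toward KO. In this exact binomial test 16 WT-only and 0 KO-only regions gave p = 0.0546, whereas 3 and 5 gave p = 0.00854. The split of 6 and 19 is therefore no sign of a lean to KO. Without KO replicate 1, 2 bands passed, and 1 passed without KO replicate 2 or without WT replicate 1. Ranked by the p of this test and not by share, the leading bands on the WT side were 7q35 (22 WT-only and 0 KO-only regions), 4q13.1 (33 and 1), 12q23.1 (31 and 1), 18q12.1 (38 and 2), 3p12.3 (29 and 1) and 6p21.1 (25 and 1). They were followed by 16q22.1, 4p15.1 and 8q21.13 (16 and 0 each) and 6p21.31 (17 and 0). Ranked the same way, the leading bands on the KO side were 8p23.1 (15 WT-only and 14 KO-only regions), 1q23.3 (17 and 13), 8p11.23 (8 and 8), 1p13.1 and 5q23.1 (9 and 8 each), 2p22.2 and 5p15.32 (3 and 5 each), 13q12.3 (7 and 7), 10q22.3 (25 and 14) and 5p15.33 (18 and 11).

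Bands that hold well-known neural genes were described as a set chosen after the genome-wide counts had been seen, and their regions were not assigned to the genes. The band of PAX6, a regulator of cortical and eye progenitors (11p13, 5.4 Mb), held 70 regions open in all 4 libraries, 28 WT-only and 4 KO-only regions. That of SIX3, a forebrain patterning factor (2p21), held 91, 32 and 5 in the same order. That of OTX2, a factor of the anterior neural plate (14q22.3), held 24, 15 and 1. Of the other forebrain bands, those of LHX2 (9q33.3), EMX2 (10q26.11), GLI3 (7p14.1) and NR2F1 (5q15) held 13 WT-only and 4 KO-only, 12 and 3, 21 and 5, and 26 and 6 regions, and those of RAX (18q21.32) and BCL11A (2p16.1) held 13 and 2, and 26 and 3. The band of NEUROG2, a proneural factor (4q25), held 59, 32 and 4, and that of NEUROD1, a neuronal differentiation factor (2q31.3), held 22, 7 and 0. The band of the pluripotency and neural progenitor factor SOX2 (3q26.33) held 31, 14 and 3. In the same group the bands of SOX1 (13q34), ZIC2 (13q32.3), POU3F2 (6q16.1) and EOMES (3p24.1) held 22 WT-only and 6 KO-only, 13 and 3, 21 and 5, and 18 and 4 regions, and that of SOX11 (2p25.2) held 4 and 1. Bands of neural crest regulators gave 27, 10 and 4 for TFAP2A (6p24.3), 26, 18 and 5 for PAX3 (2q36.1) and 63, 14 and 7 for SOX10 (22q13.1), while those of SOX9 (17q24.3), TFAP2B (6p12.3) and FOXD3 (1p31.3) held 12 WT-only and 3 KO-only, 14 and 6, and 32 and 10 regions. The band of the HOXA cluster, which patterns the hindbrain and trunk (7p15.2), held 28, 11 and 7, the lowest WT-only share of the 6 bands in its group. The others were the bands of EN2 (7q36.3), with 15 WT-only and 8 KO-only regions, of HOXB1 (17q21.32), with 8 and 3, of HOXC4 (12q13.13), with 16 and 5, of HOXD3 (2q31.1), with 30 and 6, and of EGR2 (10q21.3), with 21 and 3.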

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

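The common minimum width, the thinning, the replicate block, the ratio of WT-only to KO-only regions and the bands were chosen after seeing the data; the other settings were planned. The pair excess stayed above 1 in each setting that could give it, from 7.06 with the 50% cover rule to 14.2 at the stricter threshold, with lower bounds from 6.57 to 12.8. The ratio of list lengths was 1.28 after thinning, 1.24 to 1.47 with one library left out, and 1 by construction with equal-number lists. The Jaccard difference was 0.0538 to 0.0847 with one library left out, highest without WT replicate 1. Equal-number lists gave 5439 WT-only and 3803 KO-only regions, a ratio of 1.43, and the stricter threshold gave 1341 KO-only regions. With one library left out, WT-only regions numbered 13435 to 29291 (highest without WT replicate 1, 20870 without WT replicate 2), KO-only regions 3514 to 9757 (highest without KO replicate 1, 8523 without KO replicate 2, 4710 without WT replicate 2), and their ratio was 1.38 (without KO replicate 1) to 8.34 (without WT replicate 1), with 1.7 without KO replicate 2 and 4.43 without WT replicate 2. Leaving out a library loosens both classes by construction: the class of its genotype then needs a peak in 1 library, and the other class needs absence from 1 library. The number of chromosomes past the threshold was 0 at the stricter threshold, 2 with the 50% cover rule, with merged gaps and with the common minimum width, and 0 to 2 with one library left out (2 without KO replicate 1, 0 without each other library); the cause was not tested. Chromosome 4 was not among those past it with the cover rule or the minimum width, and its adjusted p (Fisher's exact test) ranged from 0.00101 to 0.878 over the settings. The number of bands past it was 1 with the 50% cover rule, 0.1 on average over the thinned draws, and 0 to 2 with one library left out (2 without KO replicate 1, 1 without KO replicate 2 or WT replicate 1). With the replicate number as a block, the ratio of list lengths was 1.35, from paired differences of 13293 and 21841 peaks (exact sign-flip p = 0.5, the smallest that 2 pairs can give). Paired counts of regions had one direction too: 26193 regions were in WT and not KO of replicate 1 against 12696 the other way, and 34462 against 12099 in replicate 2. A region lost in both pairs is by definition a WT-only region, so the block leaves that count as it is. The labels do not say that a number marks a shared culture. The planned promoter, gene list, single-gene and motif results were not run for want of an hg19 annotation here. Depth limits all absence calls: a region without a peak may be open below the calling threshold, and in the weakest 10th of the peaks of WT replicate 1 only 30.5% were found in WT replicate 2.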

Other observations

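The tests of overall enrichment and of narrow peaks, and the choice of developmental bands, came after the values were seen; the tests of depth, of the pair excess and of neighbouring regions were written down first. By count, the fullest 500 kb windows of WT-only regions were on chromosome 1 at 110500001 to 111000000 (1p13.3), chromosome 5 at 54000001 to 54500000 (5q11.2) and chromosome 20 at 61500001 to 62000000 (20q13.33). Each held 10 WT-only and 0 KO-only regions beside 9, 7 and 12 regions open in all 4 libraries. Permuting the class over regions found in exactly 2 libraries gave up to 13 in the fullest window (upper end of the 95% range), so no WT-only window stood out. Among KO-only windows the fullest was chromosome 1 at 117000001 to 117500000 (1p13.1), with 6 KO-only and 2 WT-only regions, and chromosome 8 at 37000001 to 37500000 (8p11.23) held 5 and 1. The upper end of the permuted range was also 6.

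Developmental bands were compared as 4 groups with all other bands. WT-only regions made up 85.1% in 10 forebrain bands (217 WT-only, 38 KO-only), 82.1% in 9 bands of neural progenitor and neuron genes, 74.1% in 6 neural crest bands (100 and 35) and 75.9% in 6 hindbrain and trunk bands. Other bands lay between 80.8% and 80.9%. Fisher's exact test gave an unadjusted p of 0.0908 for forebrain and 0.0476 for neural crest, and the smallest adjusted p over the 4 groups was 0.182. The prediction that a value above 0.05 would exclude a difference was too strong, since a band of several Mb holds many other genes; the question stays open until regions are assigned to genes.

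The shorter KO lists were set against depth. WT lists thinned to the background of a KO library, at that library's p threshold, kept between 58918 and 68529 peaks (SD of 20 draws at most 65.8), more than the longer KO list of 51105. Thinning redrew summits only, without narrowing peaks or applying a minimum width again, so it may keep peaks that a shallower library would lose. Loss of summit signal alone left part of the gap. Whether lower depth as a whole accounts for all of it could not be told. Whether enrichment over background was lower throughout the KO libraries stayed open, because the answer turned on the regions chosen. At equal background, the 5000 common regions with the highest mean log fold had median folds of 11.7 and 11.1 in WT and 11.1 and 11.2 in KO. The 5000 ranked by their lowest −log10 q had 11.3 and 10.5 in WT against 10.9 in both KO libraries. That ranking leans to regions strong in KO, since the median −log10 q over common regions was 10.6 and 11.3 in KO against 13.9 and 15.7 in WT. Over all 28147 common regions both KO medians of fold (6.96 and 7.06) lay below both WT medians (7.33 and 7.3). Cell composition, clone and culture are confounded with genotype in 2 against 2 libraries and were not tested.

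Regions found by both libraries of one genotype alone were set against list-wide factors and weak peaks. The lower bound of the pair excess was 8.34, where a library factor that acts alike on the odds of calling each region predicts 1. A library factor that acts unevenly by peak strength or width need not cancel, and was not tested. The lower bound was 68.7 where both peaks reached a −log10 q of 10, so the excess was not confined to regions whose called peaks lay near the threshold. That filter does not cover the libraries without a peak, where signal may lie just below the threshold. Calling noise at the threshold was therefore not excluded for those libraries. A genotype effect is a candidate explanation. It stays a hypothesis, because clones, culture batches or uneven library factors that follow genotype could give the same pattern.

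The leading KO-only region, 182 bp on chromosome 8, is a candidate artifact. The narrowest peaks differed between the lists, at 183 and 193 bp in WT and 170 and 178 bp in KO, and widths stopped abruptly there: the 10 bp from the narrowest width up held at least 1.00 times as many peaks as the next 10 bp in each list (lowest in KO replicate 2, 1412 against 1407), which is consistent with a minimum peak width set for each library. The number of KO-only regions narrower than the narrowest peak of either WT list was 2, 1 of them with both −log10 q values above 10. Against the narrowest peak of WT replicate 2 alone the number was 7 (0.298% of KO-only regions). These counts use the width of merged regions, which can be wider than each peak in them. With the common minimum width applied to each peak, KO-only regions went from 2347 to 2056 and WT-only regions from 9923 to 10195. A width limit could thus touch more KO-only regions than these 7, but most of the class remained.

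WT-only regions did not gather more than regions found in exactly 2 libraries do in general. A share of 33.7% had another WT-only region within 50 kb, below the 34.7% to 36.6% (95% range) of 1000 permutations of the class over regions found in exactly 2 libraries. The 9923 WT-only regions are themselves part of that pool, so gathering relative to the whole genome was not tested. The test was one-sided, for gathering, and does not assess a share below the range. KO-only regions had such a neighbour in 12.0% of cases, just above the permuted range of 8.65% to 11.9% (one-sided permutation p = 0.022, among 2 such tests). The hypothesis that KO-only sites may cluster weakly rests on a value of 11.97% against 11.93%.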
